A study of Homo sapiens with 9 samples.

How the data were processed

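The series held 9 libraries from primary human epidermal keratinocytes, the main cells of the skin epithelium, grown in EpiLife medium. For RNA-seq, 2 libraries came from cells given a control siRNA and 2 from cells given an siRNA against ELL, all collected at day 4 after knockdown in growth medium. For ChIP-seq, undifferentiated keratinocytes were crosslinked with 2 mM disuccinimidyl glutarate (DSG) and 1% formaldehyde. There were 2 libraries for ELL, 2 for RNA polymerase II (Pol II) and 1 input library, which is chromatin with no antibody step. Groups and replicate numbers were taken from the labels, which do not state that replicates came from separate cultures or donors. The p-values therefore measure only the spread between these libraries, which may be technical.

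Reads were processed by the submitters against hg19. For RNA-seq, the tools were TopHat2 2.1.0 and Partek, per the submitters' processing notes. For ChIP-seq, they were BWA 0.7.13, MACS2 2.2.4 and bedtools, per the submitters' processing notes. The gene annotation, the strand setting, the peak thresholds and the use of the input are not given in the sources used here. The deposited RNA-seq values were per-gene normalized expression on a log2 scale, 1 value per library. Which normalized unit was logged is not given in the sources used here. Tested on the file, the lowest deposited log2 value was -26.5754, which equals the log2 of 1e-08, so a constant of that size had been added before the logarithm. A value below -20 was counted as this floor, and 18 genes had at least 1 such value. Tested the same way, the 1941 listed genes were a selection. The smallest absolute difference between group means was 1.00005 on the log2 scale, a fold of 2, and the largest unadjusted p of an equal-variance 2-sample test was 0.049974. Members of a gene list outside the 1941 genes were not analysed here, and neither was the ELL transcript, so the knockdown was not checked.

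The deposited log2 values were converted back to linear normalized values. Means and SDs per group were taken on that linear scale, with n = 2. The test was limma 3.58.1 in R 4.3.3, with a trend in the variance and no covariate, on log2(value + 1) for genes with a mean of at least 1 over the 4 libraries. P-values were adjusted by Benjamini and Hochberg, with a threshold of 0.05. All log2 changes printed are ELL siRNA minus control siRNA on the log2(value + 1) scale with the limma standard error (SE), and that scale understates the change of low genes, so the ranks of the largest changes depend on the pseudocount. Because the genes had been selected for a difference between these same libraries, adjusted p-values are too small and give no genome-wide false discovery rate. A test of 2 libraries against 2 by exact permutation cannot give a p below 0.333. Read depth per library is not given in the sources used here, so the counting error behind each value is unknown. The deposited values summed over the listed genes to 21112 and 21277 for ELL siRNA and to 27578 and 26711 for control siRNA. Scaling the libraries to equal sums moved the difference of every gene up by 0.357 on the log2 scale of the linear values, and by less on the log2(value + 1) scale. Within each group, Pearson's r across genes with a mean of at least 1 was 0.997, and genes are not independent replicates. The median SD between libraries on the log2(value + 1) scale was 0.0442 for ELL siRNA and 0.0607 for control siRNA.

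Before the data were examined, 18 gene lists were fixed: mitosis and cell cycle progression, DNA replication and repair, keratinocyte differentiation and cornified envelope, basal keratinocyte identity and adhesion, p53 targets and CDK inhibitors, immediate early and EGFR ligand genes, transcription elongation factors and Pol II, interferon response, inflammatory cytokines and chemokines, mesenchymal and TGF-beta response genes, cholesterol and fatty acid synthesis, replication-dependent histones, small nuclear and nucleolar RNAs, ribosomal proteins and ribosome biogenesis, and markers of melanocytes, fibroblasts, immune and Langerhans cells, and endothelium. For the 12 lists with at least 5 listed members, the split into higher and lower was compared with that of all other listed genes by a two-sided Fisher exact test, adjusted over those lists. This test treats genes as independent, which genes of 1 pathway are not. The genes named in the text were chosen by a rule fixed at the same time: the 10 largest rises and 10 largest falls among called genes whose groups do not overlap, up to 5 called members per list with the largest absolute change, and every listed elongation factor. Some genes that the rule names are not reported here. Any other gene named is said to have been chosen after its values were seen. Another 4 lists were written after the values were seen and appear only among the closing observations. Symbols are those of the table. Of these, 1878 matched a RefSeq symbol of GRCh38.p14 and 1919 matched a symbol or a unique synonym, and that table was used for names and gene types only.

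There was 1 peak list for ELL and 1 for Pol II, with no replicate number, so peaks have no replicate error. How the replicates were combined is not given in the sources used here. Peak numbers in the ELL list reached 18391 for 6184 peaks, so the list was a selection, and its criterion is not given in the sources used here. The score of each peak is the caller's own and was deposited on a scale capped at 1000. It was used only to rank or filter peaks within a list. The caller rank of an ELL peak is its peak number, which follows the order of the scores. Overlap was counted as at least 1 bp and compared with 1000 circular shifts of the ELL peaks within each chromosome, giving a one-sided permutation p. Shares have a 95% Wilson interval, which covers counting error only. Coordinates are 1-based in hg19. Because no hg19 gene annotation was used here, peaks were not assigned to genes, and the position of peaks relative to genes and the presence of ELL peaks at genes changed by ELL siRNA were not analysed here. The rule for named peaks was the 5 with the highest score in each list. Ties at the highest score, 101 peaks for ELL and 2786 for Pol II, kept the rule from picking 5. For ELL the 5 lowest peak numbers at that score were named, and for Pol II, which has no such numbers, the 3 widest peaks at that score, both choices made after the data were seen. Calculations outside limma used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures used matplotlib 3.10.9.

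The alternatives tried were another pseudocount (0.1), no filter on low values, the replicate number as a block, each library left out in turn, an absolute log2 change of at least 1, and an adjusted p under 0.01. For the lists, an exact binomial test against 50% was tried. For peaks, the alternatives were an overlap of at least 50% of the ELL peak, peaks within 500 bp, the upper 50% of each list by score, and random shifts of 10 to 100 kb. Scaling to equal sums, the deposited log2 values with no filter, and list tests on genes with a mean of at least 1 were added after seeing the data. The limma fit, the Fisher test of the lists and the circular shifts were tested on simulated data. In a simulation of the siRNA comparison with 1146 genes, of which 200 were changed, limma recovered 94.0% of genes changed by 1.5-fold, 98.5% at 2-fold and 100% at 4-fold, with 4 false calls. The simulated noise took the SDs of the selected genes, and most simulated genes were unchanged. These rates therefore test the code and do not carry over to the real table. Of 1000 random lists of 30 genes drawn from the 1941, 2.6% passed the Fisher exact test. For 2000 simulated peaks, the ratio of observed to shifted overlap was 0.979 for unrelated lists and 7.25 with 600 planted overlaps. These peaks had 1 width per list and were spread at random, without the clusters that real peaks can form. The ratios therefore test the code only.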

Results

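ELL is an elongation factor that raises the rate at which Pol II transcribes. The study asked how ELL and Pol II act on the genes of dividing epidermal cells. RNA-seq compared keratinocytes given an ELL siRNA (n = 2 libraries) with keratinocytes given a control siRNA (n = 2) at day 4. ChIP-seq in undifferentiated keratinocytes gave 6184 ELL peaks and 6376 Pol II peaks, each as 1 list with no replicate number. The RNA table listed 1941 genes, already selected for a difference between the siRNA groups, of which 1280 were higher and 661 lower with ELL siRNA. Read depth is unknown for all libraries.

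The first comparison asked which transcripts differed when ELL was targeted, and the genes of cell division were lower. CDC20, which activates the anaphase-promoting complex, fell from 60.3 ± 0.419 in control libraries to 6.39 ± 0.962 with ELL siRNA (mean normalized expression ± SD, n = 2 per group; log2 change -3.06, SE 0.0764). PLK1, a kinase that drives mitosis, fell from 33.0 ± 1.12 to 3.25 ± 0.0778. The cytokinesis kinesin KIF20A fell from 17.2 ± 0.771 to 1.39 ± 0.0588, the spindle midzone protein PRC1 from 26.2 ± 0.0438 to 2.96 ± 0.114, and survivin (BIRC5) from 24.4 ± 1.34 to 2.82 ± 0.0222. Of 87 genes of mitosis and cell cycle progression, 80 were listed and all 80 were lower (Fisher exact test, adjusted p = 1.60e-38). Limma called 78 of the 78 members tested over all genes tested, and 78 when adjusted over the list alone, with a median log2 change of -1.87. Limma called all 1146 genes it tested in this selected table. This count of calls and those given for the later lists therefore add no support.

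Genes of DNA replication and repair fell with them. RRM2, the small subunit of ribonucleotide reductase, fell from 19.7 ± 0.0402 to 3.83 ± 0.105 (log2 change -2.10, SE 0.0711), and thymidine kinase (TK1) fell from 41.5 ± 2.36 to 9.32 ± 0.461. The replication initiation factors MCM10 and CDC6 fell from 5.59 ± 0.510 to 0.688 ± 0.147 and from 10.7 ± 0.365 to 2.18 ± 0.179. The histone chaperone ASF1B fell from 9.65 ± 0.130 to 2.67 ± 0.230. Of 81 genes on this list, 57 were listed and all 57 were lower (Fisher exact test, adjusted p = 2.47e-27). Limma called 54 of 54 over all genes tested and 54 adjusted over the list alone, with a median log2 change of -1.21.

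**Figure D1:**
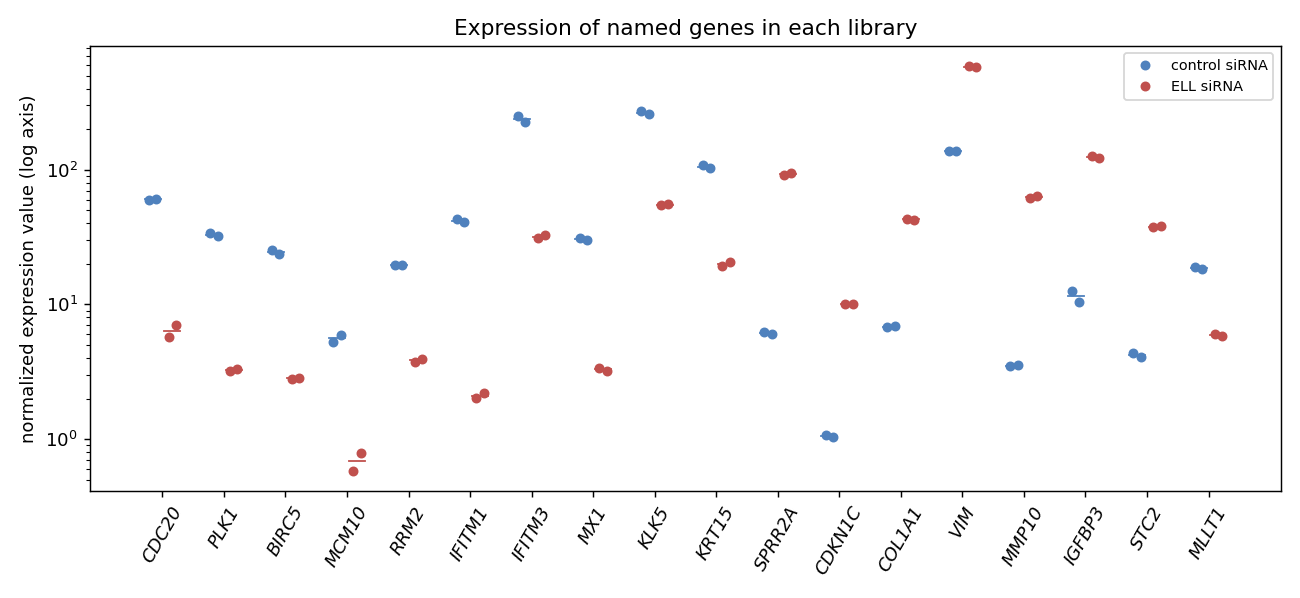
Normalized expression of 18 named genes on a log axis, with control siRNA libraries in blue and ELL siRNA libraries in red. Each point is 1 library (n = 2 per group) and each line the group mean; no gene shown has overlapping groups, and CDC20 falls from a mean of 60.3 to 6.39.

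Interferon-stimulated genes, which restrict viruses, made up 4 of the 10 largest falls on the log2(value + 1) scale, a ranking that depends on the pseudocount. IFITM1 fell from 41.9 ± 1.62 to 2.101 ± 0.126 (log2 change -3.79, SE 0.0714) and IFITM3 from 237.8 ± 17.4 to 31.9 ± 1.08. These encode related membrane proteins that block viral entry, so reads could be split between relatives. IFIT1, which binds foreign RNA, fell from 13.3 ± 0.392 to 0.859 ± 0.000256. The antiviral GTPase MX1 fell from 30.5 ± 0.746 to 3.29 ± 0.128 and the RNA-sensing enzyme OAS2 from 13.7 ± 0.698 to 1.40 ± 0.0761. Of 67 interferon response genes, 33 were listed, 31 of them lower and 2 higher (Fisher exact test, adjusted p = 1.91e-12). Both higher members, GBP2 and ISG20, had means under 1 and were not tested, at 0.197 and 0.352 with ELL siRNA against 0.0929 and 0.168 in controls. They were chosen after their values were seen. Limma called 29 of 29 over all genes tested and 29 adjusted over the list alone, all lower, with a median log2 change of -1.89.

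Keratinocyte genes moved in both directions. KRT15, a keratin of basal cells, fell from 105.3 ± 3.80 to 19.9 ± 0.924, and KRT5, the main basal keratin, fell from 8413 ± 217 to 4029 ± 34.2. The adhesion molecule BCAM fell from 17.6 ± 0.950 to 4.23 ± 0.685. The arginine synthesis enzyme ASS1 rose from 4.17 ± 0.304 to 13.7 ± 0.411. Of 49 basal identity and adhesion genes, 8 were listed, 5 lower and 3 higher, a split that did not differ from the rest of the table (Fisher exact test, adjusted p = 0.174). Limma called 7 of 7 over all genes tested and 7 adjusted over the list alone.

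Among differentiation genes, KLK5, a protease that sheds the outer layer, fell from 265.6 ± 9.63 to 54.8 ± 0.832 (log2 change -2.26, SE 0.0511). The cornified envelope genes CNFN and LCE3D fell from 14.3 ± 0.675 to 2.39 ± 0.104 and from 11.7 ± 1.08 to 1.16 ± 0.0164. SPRR2A, another envelope precursor, rose from 6.17 ± 0.138 to 92.9 ± 2.49, and its relative SPRR2D rose from 85.2 ± 1.02 to 479.3 ± 28.7. The SPRR2 and LCE3 genes have near-identical copies, so the split of reads between copies is uncertain. Of 105 differentiation and cornified envelope genes, 32 were listed, 22 lower and 10 higher (Fisher exact test, adjusted p = 0.000248). That call was lost in all 3 alternatives run on the lists, with adjusted p from 0.0614 to 0.570. Limma called 30 of 30 over all genes tested and 30 adjusted over the list alone, 20 lower and 10 higher.

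Several inhibitors of growth and stress genes were higher. CDKN1C, which encodes the CDK inhibitor p57, rose from 1.06 ± 0.0233 to 10.0 ± 0.0385 (log2 change 2.42, SE 0.0819). PMAIP1, a pro-apoptotic BCL2 relative, rose from 11.7 ± 1.25 to 44.7 ± 2.97. SESN2, GADD45B and BTG1, which respond to stress or restrain growth, rose by log2 changes of 1.79, 1.70 and 1.28. Of 45 p53 targets and CDK inhibitors, 10 were listed, with 9 higher and only CDKN2C lower, at 0.253 against 0.863 in controls (chosen after its values were seen, and not tested). This split did not differ from the rest of the table (Fisher exact test, adjusted p = 0.215). It did among genes with a mean of at least 1 and among those with an absolute log2 change of at least 1 (0.0163 and 0.0283), and against 50% the exact binomial test gave 0.0368. Limma called 8 of 8 over all genes tested and 8 adjusted over the list alone, all higher.

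Some immediate early genes also rose. The transcription factor ATF3 rose from 2.11 ± 0.149 to 11.2 ± 0.00609, KLF6 from 51.7 ± 4.08 to 146.5 ± 8.01, and JUN from 49.5 ± 4.47 to 100.7 ± 0.873. The phosphatase gene DUSP1 and the AP-1 member FOSL2 rose by log2 changes of 1.47 and 1.04. Of 42 immediate early and EGFR ligand genes, 7 were listed, with 6 higher and EGR3 lower at 0.217 against 0.611 (chosen after its values were seen, and not tested). The split did not differ from the rest (Fisher exact test, adjusted p = 0.434). With 7 members, and 65.9% of the other listed genes higher, that test had little power to find a rise. Among genes with an absolute log2 change of at least 1 the split did differ (Fisher exact test, adjusted p = 0.0283, within 0.0283 to 0.136 over the alternatives). Limma called 5 of 5 over all genes tested and 5 adjusted over the list alone. Of 59 inflammatory cytokine and chemokine genes, 12 were listed, 11 higher and 1 lower (Fisher exact test, adjusted p = 0.104, and 0.0152 to 0.204 over the alternatives). The lower gene was the chemokine CXCL14, which fell from 8.20 ± 1.17 to 0.411 ± 0.0543. BIRC3, an inhibitor of cell death induced by NF-kB, rose from 0.934 ± 0.163 to 5.32 ± 0.343. TLR2, CXCL5 and PTGS2 rose by log2 changes of 1.21, 1.08 and 1.03. Limma called 8 of 8 over all genes tested and 8 adjusted over the list alone.

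Genes of the extracellular matrix and the mesenchymal state included large rises. The matrix protease MMP10 rose from 3.51 ± 0.0245 to 62.5 ± 1.63 (log2 change 3.82, SE 0.0648). Vimentin (VIM), an intermediate filament protein of mesenchymal cells, rose from 137.1 ± 0.105 to 581.7 ± 7.52. The matrix protein POSTN rose from 0.197 ± 0.0529 to 4.21 ± 0.0678 and the collagenase MMP1 from 0.802 ± 0.0456 to 6.83 ± 0.158. Of 44 mesenchymal and TGF-beta response genes, 17 were listed, 15 higher and 2 lower (Fisher exact test, adjusted p = 0.104, and 0.000241 to 0.0163 in the 3 alternatives). The 2 lower genes, the matrix protein tenascin-C (TNC) and the myosin light chain MYL9 (log2 change -0.929), both fell in the limma test and were chosen after their values were seen. Limma called 15 of 15 over all genes tested and 15 adjusted over the list alone.

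Some markers of other cell types were in the table too, in both directions. Of 16 fibroblast markers, 7 were listed, 6 higher and 1 lower (Fisher exact test, adjusted p = 0.434). COL1A1, which encodes the main chain of type I collagen, rose from 6.82 ± 0.0662 to 42.8 ± 0.580, and COL1A2, S100A4 and FBN1 rose by log2 changes of 1.27, 1.16 and 1.01, while MFAP5 fell from 54.4 ± 0.572 to 17.9 ± 1.11. Limma called 6 of 6 over all genes tested and 6 adjusted over the list alone. Of 16 immune and Langerhans cell markers, CD68 was the 1 listed and rose from 4.56 ± 0.657 to 9.64 ± 0.256, called over all genes tested and adjusted over the list alone. Of 10 endothelial markers, 2 were listed and higher. ENG rose from 1.25 ± 0.144 to 2.74 ± 0.304 and was the 1 member tested, called over all genes tested and adjusted over the list alone, and TEK stood at 0.0488 against 0.0166. Of 12 melanocyte markers, 2 were listed and neither was tested, with MLANA at 0.0237 against 0.177 and GPR143 at 1.05 against 0.346. TEK, MLANA and GPR143 were chosen after their values were seen.

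The listed genes of lipid synthesis and ribosome assembly, a minority of each list, fell. INSIG1, a regulator of sterol synthesis, fell from 36.6 ± 0.0398 to 8.02 ± 0.190. HMGCS1, FADS2 and DHCR7 fell by log2 changes of -1.35, -1.14 and -1.03. Of 35 cholesterol and fatty acid synthesis genes, 6 were listed and all 6 were lower (Fisher exact test, adjusted p = 0.00307), and limma called 6 of 6 over all genes tested and 6 adjusted over the list alone. FBL, which methylates ribosomal RNA, fell from 69.7 ± 2.70 to 13.1 ± 0.188, and the nucleolar proteins NCL, NOLC1, NPM1 and NOP16 fell by log2 changes of -1.41, -1.39, -1.24 and -1.004. Of 40 ribosomal and ribosome biogenesis genes, 7 were listed and all 7 were lower (Fisher exact test, adjusted p = 0.00125), with 7 of 7 called over all genes tested and 7 adjusted over the list alone. Both calls were lost among genes with an absolute log2 change of at least 1, at adjusted p of 0.0692 and 0.112. The lowest adjusted p over the alternatives was 0.0195 for the lipid genes and 0.0162 for the ribosome genes. The genes named here had means of at least 8, a level at which only 36.7% of listed genes were higher (137 of 373). In the Fisher tests 66.1% and 66.2% of the other genes were higher, so level may account for part of these splits. The lists were not tested against genes of similar level.

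Few genes of the transcription machinery were listed. Of 71 elongation factor and Pol II genes, only 2 were in the table. MLLT1, a reader of acetylated histones in the super elongation complex, fell from 18.6 ± 0.400 to 5.91 ± 0.176 (log2 change -1.50, SE 0.0696). TCEA2, a member of the TFIIS family, rose from 1.34 ± 0.323 to 3.13 ± 0.285 (log2 change 0.83, SE 0.1003). Both were called over all genes tested and adjusted over the list alone. Of 57 replication-dependent histone genes, 4 were listed and all were higher. H2BC5 rose from 5.13 ± 0.807 to 17.4 ± 1.02, and H4C8, H2BC12 and H2BC11 rose by log2 changes of 1.57, 0.98 and 0.77, with 4 of 4 called over all genes tested and 4 adjusted over the list alone. Histone genes have near-identical copies, so these values are uncertain. The other 53 members were not listed, so these 4 do not show the direction of the list as a whole. Of 28 small nuclear and nucleolar RNA genes, the 1 listed was GAS5, a host of nucleolar RNAs, which rose from 2.25 ± 0.553 to 9.50 ± 0.663 and was called over all genes tested and adjusted over the list alone. Lists with fewer than 5 listed members were not tested for direction.

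**Figure D2:**
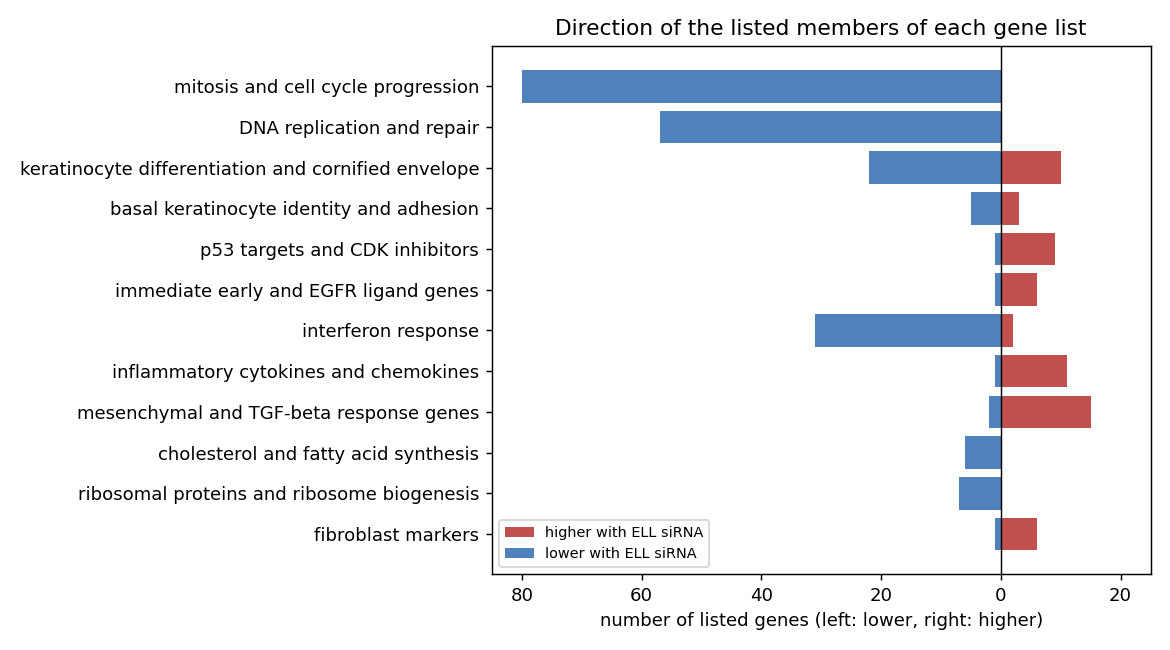
Number of listed genes that were higher (right, red) or lower (left, blue) with ELL siRNA in each of the 12 fixed gene lists with at least 5 listed members. All 80 listed mitosis genes and all 57 listed replication and repair genes were lower, whereas 15 of 17 mesenchymal genes were higher.

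Outside the lists, the largest falls on the log2(value + 1) scale included the skin growth factor-like genes IGFL3, from 29.3 ± 0.797 to 1.03 ± 0.275 (log2 change -3.91, SE 0.0882), and IGFL1, from 22.6 ± 0.0346 to 2.21 ± 0.0158. The gap junction gene GJA5 fell from 11.2 ± 0.861 to 0.443 ± 0.0469. The largest rises on that scale included the insulin-like growth factor binding protein IGFBP3, from 11.5 ± 1.59 to 124.3 ± 2.08, and the growth factor IGF2, from 0.359 ± 0.111 to 9.01 ± 0.0329. The secreted hormone STC2 rose from 4.201 ± 0.215 to 37.7 ± 0.214 and the laminin-related NTN4 from 4.23 ± 0.292 to 31.2 ± 0.471. ADAMTS14, which trims procollagen, rose from 0.404 ± 0.0403 to 14.7 ± 0.196. The receptor GPRC5B, the transcription factor CREB3L1 and the HLA class I gene HLA-G rose by log2 changes of 2.67, 2.60 and 2.59. Their control means were low, at 0.203, 0.0655 and 0.401, so the size depends on the pseudocount. On the deposited log2 scale the differences were 5.03, 6.39 and 4.30. IGFL and HLA genes have close copies, so the split of reads is uncertain.

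Limma called all 1146 genes with a mean of at least 1, with 601 higher and 545 lower. The majority turned at an absolute log2 change of at least 1, with 302 higher and 403 lower, and at a mean of at least 8 (a level chosen after the data were seen), with 137 higher and 236 lower. The first of these thresholds also sorts by level, because every listed gene differed by at least 1.00005 on the deposited log2 scale. The genes it removes fell under 1 only through the added pseudocount, which shrinks the change of low genes most. All 1941 listed genes had groups that did not overlap, against 33.3% by chance, but the table had been selected for such genes.

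The second comparison asked whether ELL sat at the same genomic places as Pol II, and many ELL peaks did. Of 6184 ELL peaks, 2361 overlapped a Pol II peak, a share of 38.2% (95% Wilson interval 37.0 to 39.4). Circular shifts of the ELL peaks gave a mean of 42.6 overlapping peaks (0.688%) and at most 77, so the observed number was 55.5 times the mean of the shifts. The one-sided permutation p was 0.001, the smallest that 1000 shifts can give. In the other direction, 1516 of 6376 Pol II peaks overlapped an ELL peak, or 23.8% (22.7 to 24.8), 39.8 times the mean of the shifts. When ELL peaks were moved by only 10 to 100 kb, the shifted overlap was higher, at 3.98%, and the observed number was 9.60 times that. The permutation p was again 0.001.

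The 5 ELL peaks with the lowest peak numbers, among 101 that shared the highest score, all overlapped Pol II peaks. They lay on chromosome 1 from 28974351 to 28976062, on chromosome 22 from 43010048 to 43012219, on chromosome 1 from 148240795 to 148242250, on chromosome 2 from 122287212 to 122289757, and on chromosome 15 from 65587903 to 65590770 (hg19). The 3 widest Pol II peaks at the highest score also overlapped ELL peaks. These were chromosome 1 from 183168420 to 183226646, chromosome 18 from 21492088 to 21544774, and chromosome 1 from 209778466 to 209828214, with widths of 58227, 52687 and 49749 bp.

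ELL peaks were narrower than Pol II peaks. The median width was 349 bp for ELL (quartiles 253 and 587) and 1444 bp for Pol II (quartiles 880 and 2602). The median score was 58 for ELL and 928.5 for Pol II, each on the scale of its own list. ELL peaks in a Pol II peak had a median width of 627 bp and a median score of 80, against 283 bp and 52 for the other ELL peaks. Pol II peaks with an ELL peak had a median width of 2284 bp against 1275 bp for those without. With ELL peaks placed in 10 groups by caller rank, 80.1% of the highest group and 17.5% of the lowest overlapped Pol II, and the order between was uneven, with 36.2% in group 7 and 6.79% in group 8. With Pol II peaks placed in 4 groups by width, the share with an ELL peak was 8.85%, 17.6%, 26.8% and 41.9% from narrowest to widest. Wider peaks also overlap more by chance, at 0.269%, 0.375%, 0.516% and 1.23% in the shifts. Because the lists carry no replicate number, no replicate error stands behind these shares.

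**Figure D3:**
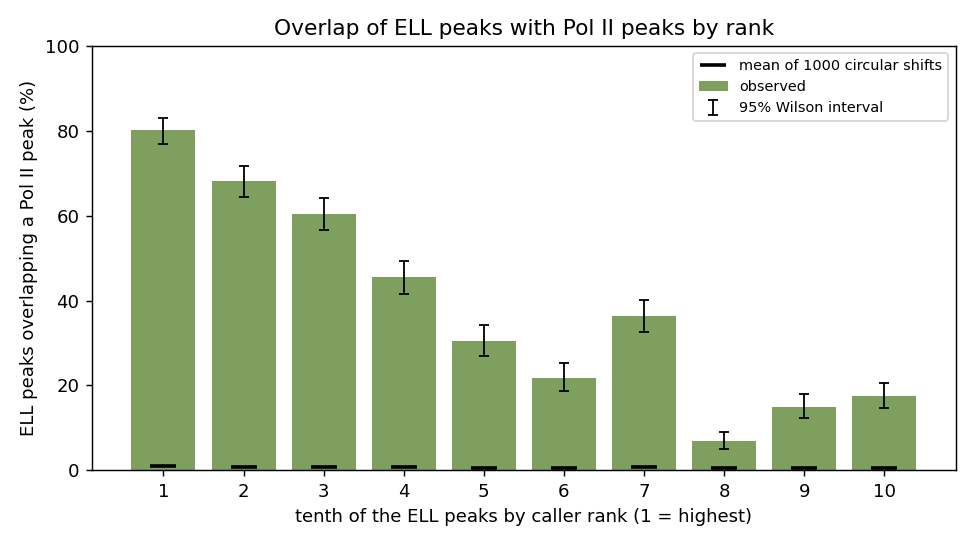
Percent of ELL peaks that overlapped a Pol II peak, in 10 groups by caller rank from highest (1) to lowest (10). Bars are observed shares, error bars their 95% Wilson intervals and short black lines the mean of 1000 circular shifts; the share was 80.1% in group 1 and 17.5% in group 10.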

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

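The direction and the call of the 111 genes with a fit that the naming rule took or that were chosen later were compared over 1221 alternative values, and none was reversed, in a table where every listed gene differed by at least 1.00005 on the deposited log2 scale. The 8 of these that lost their call did so only under an absolute log2 change of at least 1. TNC and MYL9, also chosen later, were outside this comparison. Both lost their call at that threshold, where the mesenchymal list kept 11 higher and 0 lower genes. Limma called 1146 genes with pseudocount 0.1, an adjusted p under 0.01, equal sums (added after seeing the data), and without each library in turn (1146 to 1146, where the lone library of a group is assumed to vary like the others). The replicate number used as a block also gave 1146 calls and changed none. Because the table was selected for a difference between these libraries and all 1146 tested genes were called, these counts could hardly move and say little about stability. The differences between replicates 1 and 2 correlated across genes by 0.0424 between the groups. That value gave no sign of pairing by number, but it cannot exclude a shared culture, donor or day. No filter gave 1921 calls, 65.9% higher, and the deposited log2 values with no filter (added after seeing the data) gave 1940. Both settings tested 1941 genes, and the second also changed the scale. An absolute log2 change of at least 1 left 705, of which 302 were higher and 403 lower (42.8% higher against 52.4% in the main test), by its own threshold. On the log2(value + 1) scale that threshold also removes low genes, so the turn is not one of size alone. The list values that follow are the percent of members higher and the adjusted p. With an absolute log2 change of at least 1, the differentiation list was no longer past the threshold at 34.8% (0.570), nor were the lipid list at 0% (0.0692) and the ribosome list at 0% (0.112). All 6 listed lipid genes stayed in this setting, where 43.2% of the other genes were higher, against 66.1% in the main test. In the same setting, the p53 and immediate early lists passed at 100% (0.0283 each) and the mesenchymal list at 100% (0.000241). The exact binomial test against 50% lost the differentiation list at 31.3% (0.0668) and called the p53 list at 90% (0.0368), the inflammatory list at 91.7% (0.0152) and the mesenchymal list at 88.2% (0.00705). With a mean of at least 1 (added after seeing the data), the differentiation list was lost at 33.3% (0.0614), and the p53 list at 100% and the mesenchymal list at 86.7% passed (0.0163 each). These settings change the split a list is compared with, from 66.5% higher for the differentiation list to 43.1%, 50% and 52.96%, and any further cause was not tested. The mitosis, replication and interferon lists passed in each of these settings. Overlap of ELL with Pol II peaks was 37.4% to 48.2% over the other overlap and score settings, with a permutation p of 0.001 in each. The share of Pol II peaks with an ELL peak was 23.3% to 31.4%. In the upper 50% by score, the observed number was 95.2 times the mean of the shifts for ELL and 73.5 for Pol II. The main setting gave 55.5 and 39.8. In the upper 50% of each list by score, the median width was 510 bp for ELL and 2026 bp for Pol II, and the cause was not tested. Not run were the alternatives planned for counts, the set tests that need every gene (the table held selected genes only), the promoter windows and the assignment of peaks to genes (no hg19 annotation was used here), and the ELL transcript, which was not analysed here. Depth is unknown, so its limit on low genes cannot be given.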

Other observations

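All tests in this part, and the genes and lists in it, were chosen only after the results were seen. Some targets of ATF4, the transcription factor of the integrated stress response, rose with ELL siRNA. Of 39 such genes written as a list, 16 were listed and 23 were not, and limma called all 16 higher, with a median log2 change of 1.58. Because the list was written after the values were seen, its direction has no independent test. CHAC1, which breaks down glutathione, rose from 4.70 ± 0.766 to 28.6 ± 1.61, and ASNS, which makes asparagine, rose from 7.30 ± 0.329 to 27.0 ± 0.0644 (mean normalized expression ± SD, n = 2 per group). PPP1R15A, DDIT3 and TRIB3, which act in the same response, rose by log2 changes of 1.89, 1.38 and 1.16. Of 25 chaperones of the endoplasmic reticulum and cytosol, only 4 were listed, and these 4 fell, with no test of direction. HSPA5 fell from 351.6 ± 8.13 to 132.8 ± 2.94 and HSP90B1 from 406.1 ± 1.87 to 168.9 ± 5.78, and CANX and SDF2L1 fell by log2 changes of -1.32 and -1.33.

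Of 16 glycolysis genes, 4 were listed and all 4 fell, among them GAPDH from 970.7 ± 36.9 to 441.6 ± 1.18 and PGAM1 from 144.5 ± 1.02 to 49.0 ± 1.02. GAPDH is widely used as a reference gene, and it did not hold steady on this normalized scale, whose unit is unknown. GAPDH, PGAM1 and the 4 chaperones had means of at least 8, where only 36.7% of listed genes were higher (137 of 373). Level may therefore account for part of these falls. Of 15 circadian clock output genes, 5 were listed and all 5 rose, including the repressor NR1D1 from 2.78 ± 0.765 to 12.8 ± 0.0183 and CIART from 1.27 ± 0.0331 to 7.26 ± 0.730. Among all other listed genes 65.9% were higher. With all 5 higher, the most extreme rise possible, the Fisher exact test gave an adjusted p of 0.173. A list of this size could therefore not pass for a rise, and the test decides nothing. IFNK, an interferon made by keratinocytes, fell from 9.30 ± 0.199 to 1.54 ± 0.489 (log2 change -2.03, SE 0.105). SRM, the spermidine synthase and a growth-related enzyme, fell from 90.8 ± 8.81 to 13.1 ± 1.58, and the epithelial keratin gene KRT8 fell from 254.1 ± 9.52 to 105.5 ± 3.55.

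The fall of the interferon genes may have technical or biological sources. Scaling to equal sums left the median log2 change of the tested members at -1.55, against -1.89 before. The sums cover only genes selected for a difference. KRT5 alone, at 8413 in controls and 4029 with ELL siRNA, made up much of the gap between them. The shift is therefore no measure of a library-wide offset. Equal-sum scaling moves a gene by at most 0.357 on the log2 scale. An offset of that size is therefore not the whole cause, and a larger difference in scaling was not tested. Noise of low genes was argued against, because 100% of the members with a mean of at least 1 (29 of 29) were lower. A different innate response to the 2 siRNAs and an effect of ELL itself cannot be told apart, because there were 0 libraries of untransfected cells here and each arm has 1 siRNA label. The effect of ELL on IFNK or its targets stays open, as untested.

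Low-level genes were mostly higher with ELL siRNA, and high-level genes mostly lower. Only 18 genes had a floor value, 15 of them higher, too few to make up such a tilt. Leaving them out could therefore hardly move the share of genes with a mean under 1 that were higher. It was 85.4% with them and 85.5% without (664 of 777, 95% Wilson interval 82.8 to 87.8). A common scaling offset as the whole cause was argued against, because only 36.7% of genes with a mean of at least 8 were higher (137 of 373, 32.0 to 41.7). An effect of the ELL knockdown, and a background signal in the ELL siRNA libraries, stay open as untested.

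Most ELL peaks, 3823 of 6184, lay outside Pol II peaks. Marginal ELL calls are a candidate explanation, since the share in a Pol II peak was 4.585 times as high in the top rank group as in the bottom one. The top group was also wider (median 1765 against 286 bp), but its overlap still stood 77.2 times above the shifts, against 28.0 times in the bottom group. Narrow Pol II borders were argued against, because only 2.98% of the outside peaks (114) lay within 500 bp of a Pol II peak. The lowest score in the Pol II list was 540 on that list's own scale, and 43.7% of its peaks stood at the cap of 1000. An ELL peak over a weaker Pol II site left out of that list would count as outside, which was not tested. The depth and the peak thresholds behind each list stay open, and no biological explanation was tested.

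A further hypothesis was that noncoding genes were more often higher than coding genes at a similar level. Below a mean of 1, this was not found, with 86.2% of 123 lncRNA genes and 85.3% of 621 protein-coding genes higher (two-sided Fisher exact p = 0.889). At a mean of 1 to under 8, 90.9% of 33 lncRNA genes were higher (30 genes, 95% Wilson interval 76.4 to 96.9) against 57.9% of 726 coding genes (Fisher exact p = 8.07e-05), so an excess may hold at that level, and the difference between levels was not tested. The strand setting is not given in the sources used here, so reads of lncRNA genes and of overlapping genes are not separated.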
